A study of Mus musculus with 6 samples.

How the data were processed

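Total RNA of N2a cells for 6 libraries was extracted with Trizol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The labels put 3 libraries in the wild-type group and 3 in the knockout group. The submitters' processing notes list Bowtie2 2.2.3, HISAT2 2.1.0, HTSeq 0.6.0 and the build mm10, with no role for any of them. The deposited file is a table of splicing events laid out as rMATS writes it, per the file headers, and the version and annotation behind it are not given in the sources used here. For each event the authors gave whole-number counts of reads on the inclusion and skipping junctions of each library, the length of each form, an inclusion level from 0 to 1, a p-value, an adjusted p and the difference between the mean levels, per the file headers. The counts in the deposited table cover junctions only.

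The table names its columns sample 1 and sample 2, each with 3 libraries, and no label or header ties either name to a genotype. They were kept as set 1 and set 2, no genotype was inferred from any value, and the libraries within a set carry no replicate number. All columns of per-library values were used. Checks on the table found 3 values in every list of counts or levels. Inclusion levels recomputed from counts and form lengths differed from the deposited ones by at most 0.0005, and the deposited adjusted p equalled a Benjamini-Hochberg adjustment within each kind of event to within 5e-13. Coordinates were compared with GENCODE vM21 (GRCm38, the assembly of build mm10): 99.91% of events lay inside the annotated gene, 9585 of 9594 gene IDs matched, and 99.88% of skipped exons had the ends of an annotated exon. Coordinates are 1-based and annotations (coding, UTR) are those of any transcript of the gene. For mutually exclusive exons, which exon counts as included follows the table and is not interpreted.

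Events with a mean count of 20 or more over the 6 libraries were tested, 39419 of 45595 (86.5%). The test planned before the data were examined, a quasi-likelihood test of edgeR, was not used. A moderated quasi-binomial test on the same inclusion and skipping counts took its place, written in R 4.3.3 with limma 3.58.1. It compares the 2 sets by the binomial deviance, divides by a dispersion that is moderated along the count of the rarer form and never set below 1, and is fitted within each kind of event, with Benjamini-Hochberg adjustment over all kinds. A called event had an adjusted p under 0.05 and a change in inclusion level of 0.10 or more. The dispersion prior was written in 3 forms and each was run on the data before the last was settled on: along the total count (19 events called), along the count of the rarer form from events with 1 or more such reads (11 events) and from events with 5 or more such reads (0 events, the form reported). The last form was chosen because binomial deviances shrink where few reads are expected, and the choice was made after the counts of the first 2 were known; all 3 counts are therefore given. On simulated skipped exons the reported form gave an unadjusted p under 0.05 for 2.1% of unchanged events, 1 false call, and 2, 11, 18 and 39 of 50 events recovered for changes of 0.1, 0.2, 0.3 and 0.4. The changed exons were drawn from those with middle shares of inclusion reads. Changes were made in that share, not scaled by form length, and recovery asked for an adjusted p under 0.05 with no minimum change. Limma on logit inclusion levels, held between 0.01 and 0.99, was run beside it.

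Because the quasi-binomial test called no event, the rule for named events, the direction test and the gene lists were applied to the authors' calls, for named events those with a mean count of 20 or more, a step chosen after the results were seen. It takes Hnrnpdl and Hnrnpd; the 12 largest rises and 12 largest falls, 1 event per gene, among events whose 3 libraries of a set all lie above or all lie below the other 3; the 2 events of smallest p of each kind; and up to 4 genes per gene list. The p-values, adjusted p and calls credited to the authors' deposited table are theirs, and levels of sets are means with the range of the 3 libraries. Directions were tested with exact binomial tests on 1 event per gene, and the 16 gene lists with Fisher's exact test (scipy 1.17.1), with Benjamini-Hochberg adjustment.

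Junction totals per gene had been planned only for another file layout and were added. For each gene the event with the most reads stood for it, genes with a mean count of 20 or more were kept (8285), counts were scaled by the library's sum over genes (CPM) and tested as log2(CPM + 1) with limma and a mean-variance trend, in a fit of 3 against 3 libraries. Such a total follows expression and splicing of that event together, and a log2 ratio on this scale understates the change of genes with few reads. Gene lists were tested with camera. On simulated totals of 8285 genes the test recovered 16 of 67, 55 of 67 and 65 of 66 genes changed by 1.5, 2 and 4-fold, with 11 false calls. Actb and Actg1, Akr1c12 and Akr1c13, and other near-identical genes can share reads; Gm45861 and Gm1698, and Ctsd and AC034099.1, overlap on the genome. The same rule named genes by their totals. Gene positions were tested by medians of 5 Mb windows with 8 or more genes against 1000 permutations of the genes, an analysis added after the values were seen. A list of actin genes, written after called genes were seen, was also tested with camera.

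Alternatives were other count minimums, other minimum changes, adjustment within kinds, limma, the authors' own calls and leaving out each library, and for totals median-of-ratios scaling, no filter, a pseudocount of 0.1 and leaving out each library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.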

Results

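Splice junction reads were measured in 6 RNA-seq libraries of Neuro-2a (N2a) cells, a mouse neuroblastoma line. Per the labels, 3 libraries came from wild-type cells and 3 from cells in which Hnrnpdl was knocked out. Hnrnpdl encodes hnRNP DL, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family and a paralogue of hnRNP D (AUF1). The question of the series was how alternative splicing differs between the knockout and control cells. The deposited table listed 45595 splicing events in 9594 genes, with reads on the junctions of the inclusion form and of the skipping form in each library. The table arranges the libraries in 2 sets of 3 and does not say which set is the knockout. The sets are therefore called set 1 and set 2 throughout, and every difference is given as set 1 against set 2, with no genotype attached. Junction reads summed over all events, in which a read can be counted in several events, came to 16707466, 14037425 and 13573870 in the libraries of set 1. They came to 18185394, 14245004 and 13501749 in those of set 2. The labels do not say whether the libraries of a group came from separate cultures, so p-values of the quasi-binomial and limma tests measure only the spread between these libraries. The exact binomial, Fisher's and permutation tests and the random lists take genes as independent units. Their p-values hold no spread between libraries, and 1 library can shift many genes together.

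Junction reads of Hnrnpdl (chromosome 5, 100033577 to 100039664) were present in all 6 libraries. Its most covered event had 2014, 1806 and 1760 reads in set 1 and 2569, 2146 and 2034 reads in set 2. Scaled to library totals (CPM) the means were 419.5 and 490.3, a log2 ratio of −0.22 ± 0.09 (SE, 3 libraries per set). All 3 libraries of set 1 lay below those of set 2, but the difference did not pass the limma test (adjusted p = 0.392). The labels do not give the kind of knockout, so these reads neither check the knockout nor speak against it. None of the 5 skipped-exon events of Hnrnpdl passed the quasi-binomial test either. The 105-base exon at 100035635 to 100035739, annotated as UTR, had a mean inclusion level of 0.419 in set 1 (0.367 to 0.477) and 0.445 in set 2 (0.394 to 0.496). The coding exon at 100036481 to 100036651 had mean levels of 0.992 and 0.984, and the smallest adjusted p of the quasi-binomial test over the Hnrnpdl events was 0.754. The paralogue Hnrnpd had a log2 ratio of 0.04 ± 0.13 (SE) in junction total, with a limma adjusted p of 0.976. Its 147-base exon at 99963731 to 99963877 was included at mean levels of 0.552 and 0.553.

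The first comparison asked which splicing events differed in inclusion level between the sets. In the authors' deposited table, 294 events in 252 genes passed an adjusted p of 0.05 together with a change in inclusion level of 0.10 or more. Of these, 163 had higher and 131 had lower inclusion in set 1. Skipped exons made up 224 of them, retained introns 28, mutually exclusive exons 16, alternative 3′ splice sites 15 and alternative 5′ splice sites 11. In the authors' deposited table, called skipped exons were more often higher in set 1, in 120 of 194 genes (exact binomial test, two-sided, adjusted p = 0.00589). Called retained introns were more often lower in set 1, in 21 of 28 genes (adjusted p = 0.0314). Neither direction passed among events with an authors' adjusted p under 0.01, where 58.3% of skipped-exon genes (adjusted p = 0.312) and 50% of retained-intron genes (adjusted p = 1.0) were higher in set 1. That of skipped exons passed with a change of 0.20 or more (65.6%, adjusted p = 0.0144), a mean count of 20 or more (64.7%, adjusted p = 0.00428) and no minimum change (63.5%, adjusted p = 6.28e-06). That of retained introns did not pass with a change of 0.20 or more either (42.9%, adjusted p = 0.988), but it did with a mean count of 20 or more, where 6.25% were higher (adjusted p = 0.00259), and with no minimum change (20%, adjusted p = 2.17e-05). The other kinds did not pass the test, with 4 of 16 genes higher in set 1 for mutually exclusive exons, 7 of 14 for alternative 3′ sites and 4 of 11 for alternative 5′ sites (adjusted p = 0.128, 1.0 and 0.686). A moderated quasi-binomial test on the same reads estimates the spread between libraries. Of the 294 events called in the authors' deposited table, 171 had a mean count of 20 or more. The quasi-binomial test called 0 of the 39419 events with such a mean count. Of these events 1282 had an unadjusted p under 0.05, and limma on logit inclusion levels also called 0, with 1302 at an unadjusted p under 0.05. Both numbers are below a share of 0.05 of the events, the share that p-values spread evenly from 0 to 1 give without any difference. This did not hold for events with 5 or more reads on the rarer form, a setting chosen after the data were seen. There the quasi-binomial test gave an unadjusted p under 0.05 for 757 of 12139 events, 399 of 4922 among skipped exons, above that share. The low share over all events is therefore no evidence that the sets are alike. In the quasi-binomial test, 2.1% of simulated unchanged skipped exons had an unadjusted p under 0.05. Earlier forms of the quasi-binomial test, with another estimate of the spread, called 19 and 11 events, and the form reported was settled after those counts were seen. The form that called 11 called up to 12 when the 6 libraries were split in another way, and other splits were not run with the form that called 19. On simulated skipped exons with middle shares of inclusion reads, the test recovered 2, 11, 18 and 39 of 50 events changed by 0.1, 0.2, 0.3 and 0.4. Recovery of events near either end of the scale was not measured.

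Among the events of smallest p in the authors' deposited table, Hpf1, which encodes a partner of the ADP-ribosylating enzyme PARP1, had a coding exon of 160 bases (chromosome 8, 60893701 to 60893860) with a mean inclusion level of 0.866 in set 1 (0.849 to 0.894) and 0.977 in set 2 (0.96 to 1.0). The authors' deposited table gave it an adjusted p of 3.67e-12, and the quasi-binomial test an adjusted p of 0.146. A further Hpf1 exon of 99 bases, at 60896738 to 60896836, lay the other way at 0.473 in set 1 and 0.112 in set 2, on a mean of 23 reads per library. Eef1d, a subunit of the translation elongation factor 1 complex, had a 15-base exon annotated as UTR (chromosome 15, 75905886 to 75905900) at 0.0934 in set 1 (0.0418 to 0.153) and 0.264 in set 2 (0.238 to 0.298). In the authors' deposited table its adjusted p was 3.67e-12, against 0.146 in the quasi-binomial test. U2af1, the splicing factor subunit that recognises the 3′ splice site, had a coding exon of 88 bases (chromosome 17, 31654979 to 31655066) at 0.981 in set 1 (0.958 to 1.0) and 0.87 in set 2 (0.822 to 0.91). The authors' deposited table gave an adjusted p of 2.2e-11 for it, and the quasi-binomial test 0.197. For alternative 3′ sites, the event of St7 at chromosome 6, 17850357 to 17852257, stood at 0.494 in set 1 and 0.261 in set 2. For retained introns, an intron of Rpl31, a large-subunit ribosomal protein gene, at chromosome 1, 39368007 to 39368148, stood at 0.398 in set 1 (0.343 to 0.437) and 0.519 in set 2 (0.493 to 0.563).

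**Figure D1:**
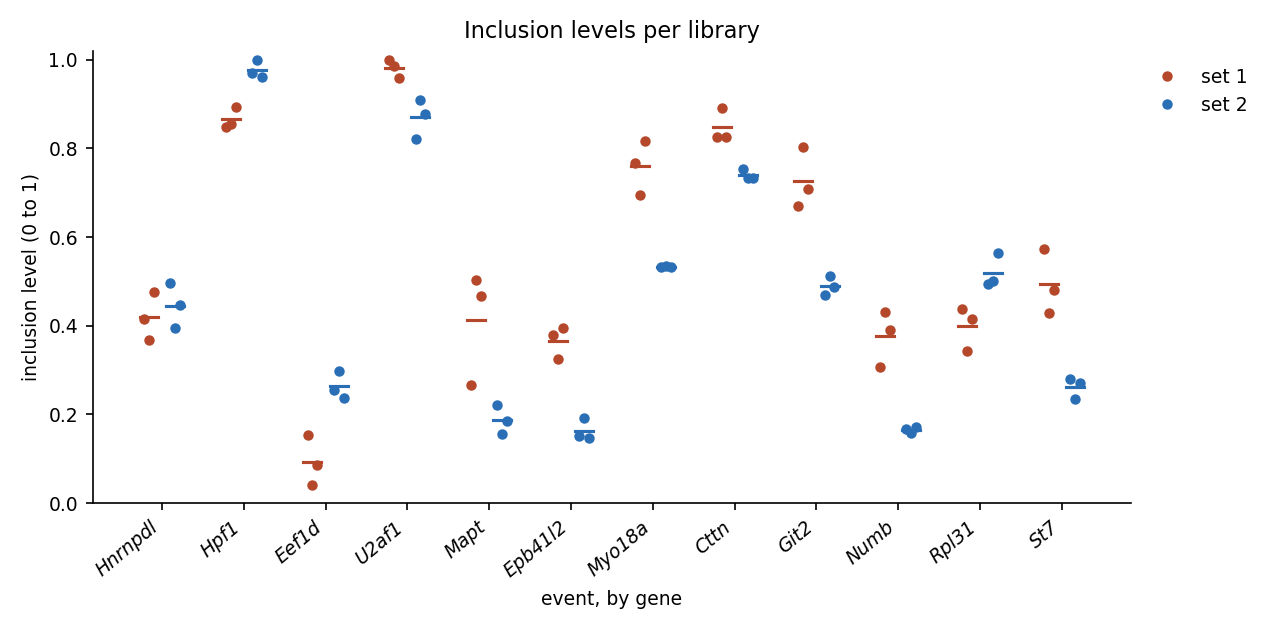
Inclusion level (0 to 1) of 12 events named in the text, 1 point per library, with a bar at the mean of each set of 3 libraries; set 1 is red and set 2 is blue. The Hnrnpdl libraries overlap between the sets, while the sets do not overlap for the other 11 genes, such as Myo18a at 0.695 to 0.816 in set 1 and 0.533 to 0.534 in set 2.

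Among events with a mean count of 20 or more whose libraries did not overlap, the largest excess in set 1 in the authors' deposited table was that of Metap1d, a mitochondrial methionine aminopeptidase gene, at 0.823 against 0.407, followed by Crlf2, a cytokine receptor gene, at 0.875 against 0.468, on means of 20.33 and 23.67 reads per library. Tnip1 stood at 0.878 against 0.506, and Fbxw11, a substrate receptor of an SCF ubiquitin ligase, at 0.744 against 0.387, where the libraries of set 1 ranged from 0.494 to 1.0. Tarbp1, Pgap2 and Ccl25 stood at 0.822 against 0.557, 0.977 against 0.723 and 0.879 against 0.546. The largest deficits in set 1 were those of an intron of 1600002H07Rik, at 0.347 against 0.697, and an exon of Gm8206, at 0.264 against 0.605, whose reads could belong to near-identical copies. A UTR exon of Usf3 stood at 0.556 against 0.865 and an alternative 5′ site of Taz, the gene of the cardiolipin-remodelling enzyme tafazzin, at 0.194 against 0.481. A retained intron of Cpt1c, a brain form of carnitine palmitoyltransferase, stood at 0.192 against 0.443. A 33-base coding exon of Ubr4 (chromosome 4, 139432482 to 139432514) stood at 0.248 against 0.437. All events of this paragraph passed the thresholds in the authors' deposited table, and none passed the quasi-binomial test (adjusted p = 0.754 for each).

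The gene lists fixed before the data were examined were compared by the genes that carried an event called in the authors' deposited table, 252 of 9590 named genes. None of the 16 lists passed Fisher's exact test after adjustment. The list of cytoskeleton and microtubule genes came closest, with 5 of 52 genes (unadjusted p = 0.0114, adjusted p = 0.183). Against 10000 random lists matched on the number of events in the table and mean count, its unadjusted p was 0.0992 and its adjusted p 1.0. Its members were Cttn, which encodes the actin-binding protein cortactin, Epb41l2, a membrane skeleton gene, Myo18a, an unconventional myosin gene, Mapt, which encodes tau, and Ank3, which encodes ankyrin G. The exon of Cttn (chromosome 7, 144450978 to 144451088) stood at 0.848 in set 1 and 0.739 in set 2, that of Epb41l2 (chromosome 10, 25501578 to 25501631) at 0.365 and 0.164, and that of Myo18a (chromosome 11, 77854678 to 77854722) at 0.759 and 0.533. The 759-base coding exon of Mapt (chromosome 11, 104298498 to 104299256) stood at 0.413 in set 1, with libraries at 0.267, 0.502 and 0.468, and at 0.187 in set 2. The level of the mutually exclusive exons of Ank3 was 0.865 in set 1 and 0.984 in set 2, a direction that is not interpreted. All 5 genes, Ank3 included, carried a called event with a higher level in set 1, and 1 of them, Ank3, also carried one with a lower level. Of 66 genes of endocytosis and vesicle traffic, 4 carried a called event (adjusted p = 0.507). An exon of Git2 stood at 0.727 and 0.489, one of Numb, which encodes an endocytic adaptor and Notch regulator, at 0.376 and 0.166, one of Dnm1, which encodes dynamin, at 0.132 and 0.009, and one of Synj1 at 0.0522 and 0.175, with 1 library of set 2 at 0.0435.

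Over all named genes, 2.63% carried an event called in the authors' deposited table. None of the lists of RNA-binding, splicing and RNA decay genes passed Fisher's exact test against this share, with a smallest adjusted p of 0.675. Of 35 nuclear speckle genes 1 was called, Acin1, with a coding exon at 0.882 in set 1 (0.78 to 1.0, so 1 library equalled set 2) and no skipping read among 136 reads in set 2, which allows a share of up to 2.21% of these reads, not scaled by form length as the inclusion levels are and for counting error only. Of 26 hnRNP genes 1 was called (Hnrnph1), of 17 SR protein genes 0, of 25 neuronal splicing regulators 0, and of 38 core spliceosome genes 2, U2af1 and Slu7, whose UTR exon stood at 0.418 in set 1 and 0.269 in set 2. Of 42 synapse genes 2 were called, Dlg3 and Cacna1b, a calcium channel subunit gene with an exon at 0.848 in set 1 (0.79 to 0.917) and 0.971 in set 2 (0.912 to 1.0). Of 54 RNA decay genes 3 were called, Dcp1a at 0.957 against 0.713, Tnrc6a at 0.25 against 0.392 and an intron of Skiv2l at 0.854 against 0.983. Of 60 DNA damage response genes 4 were called, among them Rev1, at 0.92 against 0.798. The lists of neurodegeneration-linked genes, cell cycle genes, chromatin regulators and apoptosis genes held 1 each (Mapt, Cenpa, Kdm5a and Acin1), and those of interferon response genes and markers of other cell types held 0. Adjusted over the list alone, the quasi-binomial test gave 2 events of core spliceosome genes, 1 event of hnRNP genes and 0 in each of the other lists.

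The second comparison asked which genes differed in the number of junction reads, taking for each gene the event with the most reads. Of 8285 genes, 88 passed the limma test on log2(CPM + 1), 49 higher and 39 lower in set 1. In all 88 the libraries of the sets did not overlap, and over all genes tested this held for 14.1%, where chance gives 10%. The largest rises were those of Popdc2, which encodes a membrane protein that binds cyclic AMP, with a log2 ratio of 3.76 ± 0.31 (SE, adjusted p = 5.92e-05), and Klhl4, at 3.2 ± 0.32 (SE, adjusted p = 0.000366). Gtsf1, a gene of the piRNA pathway, rose by 2.68, Apol10b by 2.5, Itga5, which encodes the fibronectin receptor subunit integrin alpha 5, by 2.4, Lix1 by 1.99 and Tnnt2, which encodes cardiac troponin T, by 1.66 on this scale. Dlk1, which encodes a transmembrane relative of the Notch ligands, had 1, 1 and 0 reads in set 1 and 261, 542 and 254 reads in set 2. Its ratio of set 2 over set 1 was 510.4, with a 95% exact (Clopper-Pearson) interval of 140.9 to 4220.0 for counting error only. Greb1 fell by 2.43, Dbh, which encodes the enzyme that makes noradrenaline from dopamine, by 2.37 and Fst, which encodes the activin-binding protein follistatin, by 2.3 on the log2 scale. The log2 ratios were −2.22 for Htr3a, a serotonin receptor subunit gene, and −1.98 for Tert, which encodes the telomerase catalytic subunit. The limma adjusted p was 0.00125 for Greb1, 0.00347 for Dbh, 0.0187 for Fst, 0.00195 for Htr3a and 0.0194 for Tert.

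**Figure D2:**
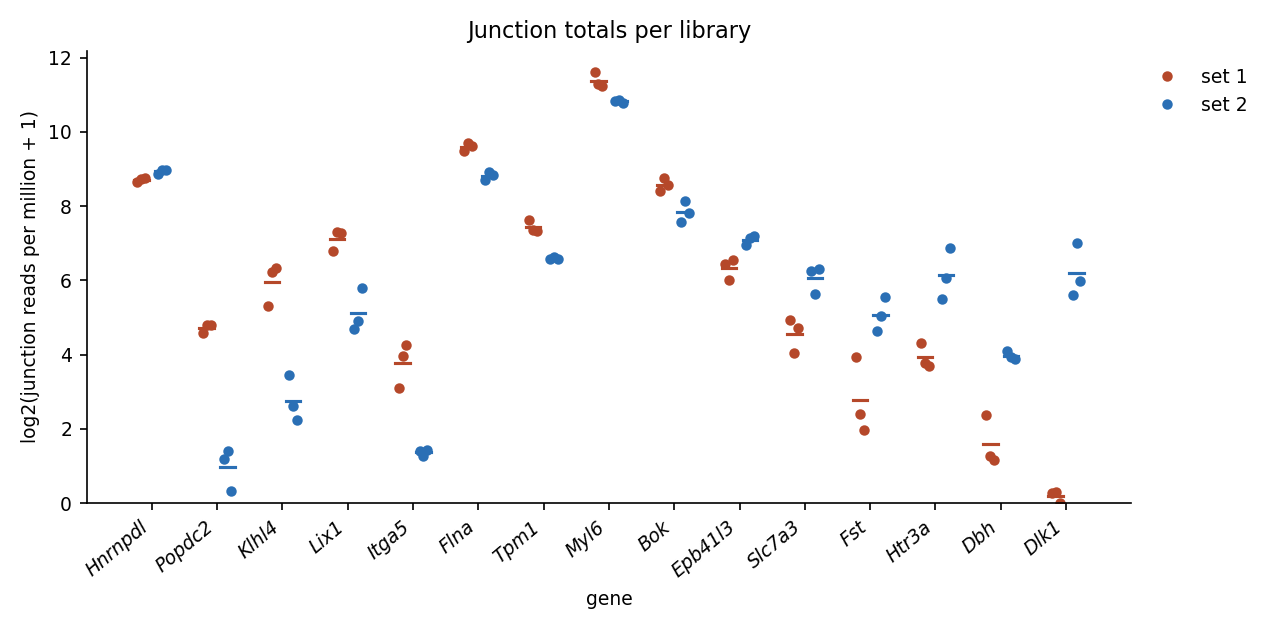
Junction reads on the most covered event of 15 genes as log2(CPM + 1), 1 point per library, with a bar at the mean of each set of 3 libraries; set 1 is red and set 2 is blue. Popdc2 had 116, 113 and 110 reads in set 1 and 7, 7 and 1 in set 2, and Dlk1 had 1, 1 and 0 in set 1 and 261, 542 and 254 in set 2.

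Of 50 measured genes of the cytoskeleton and microtubule list, 5 differed in junction total, 6 when adjusted over the list alone. Flna, which encodes the actin crosslinker filamin A, rose by 0.78 ± 0.1 (SE), Tpm1, which encodes a tropomyosin, by 0.84 ± 0.12 and Myl6, a myosin light chain gene, by 0.55 ± 0.1, while Epb41l3 fell by 0.77 ± 0.15 on the log2 scale. Of 25 apoptosis genes, Bok, which encodes a relative of BCL2, rose by 0.74 ± 0.14 (limma adjusted p = 0.0237), and 2 genes passed when adjusted over the list alone. The other 14 lists held no gene that passed over all genes, including those of 35 nuclear speckle, 26 hnRNP, 17 SR protein and 39 core spliceosome genes; adjusted over the list alone, RNA decay gave 2 genes and the DNA damage response and neurodegeneration-linked lists 1 each. No list passed the camera test, in which the smallest adjusted p was 0.323, and 0.533 with an estimated correlation. Only 2 of 30 listed markers of other cell types were measured. Library 1 of set 1 stood apart from the other libraries of its set on the first principal component (40.1% of the variance), at −5.84 against 18.35 and 22.0, with set 2 between −18.01 and −7.67. On the second component (26.7%), library 1 of each set lay lowest, at −18.88 in set 1 and −8.91 in set 2, with the other libraries between −0.96 and 16.76. Without library 1 of set 1, 287 genes passed, and leaving out another library in turn gave 25 to 72, so the number depends on single libraries.

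The genes that differed in junction total were unevenly spread over the chromosomes. Chromosome 13 held 20 of the 88 among its 286 tested genes, 6.99%, and no other chromosome held more than 8 (Fisher's exact test, two-sided, chromosome 13 against the rest, p = 1.1e-11; neighbouring genes are not independent). The region was singled out after its values were seen. From 70 Mb to the end of the chromosome, 106 of 115 genes lay below 0, with a median log2 ratio of −0.58 against 0.01 for all other genes, and 11 of the 115 passed the test, all lower in set 1. They included Tert, Clptm1l, Sdha, which encodes a subunit of succinate dehydrogenase, Tbca, a tubulin folding gene, and Fst. The window from 5 to 10 Mb lay the other way, with a median of 0.64; of its 4 genes that passed, Idi1, Gtpbp4 and Larp4b were higher and Pfkp was lower in set 1. Before this stretch of higher genes, all 10 genes tested at the start of the chromosome lay below 0, among them Akr1c12 at −1.48 and Akr1c13 at −0.87. Of 347 windows of 5 Mb with 8 or more genes over the genome, 7 passed a permutation test of gene positions at 0.05, and all 7 lay on chromosome 13. Relative to each gene's mean over the libraries, the region stood at 0.1, −0.41 and −0.59 in the libraries of set 1 and at 0.25, 0.33 and 0.33 in those of set 2.

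**Figure D3:**
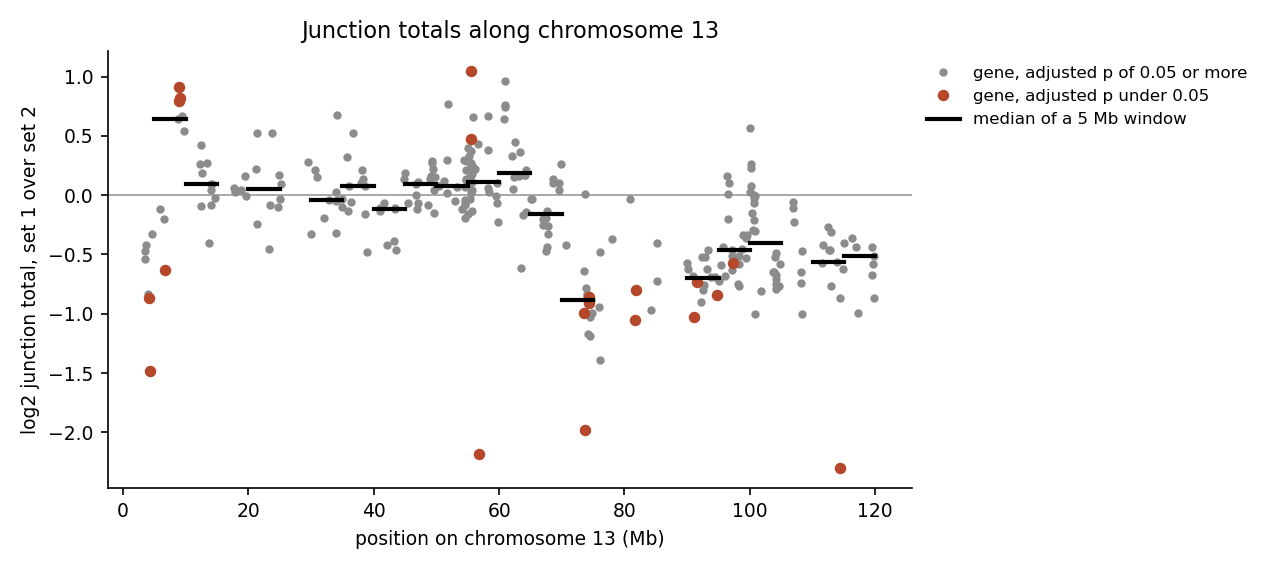
Log2 ratio of junction totals, set 1 over set 2, for the 286 genes tested on chromosome 13 by position in Mb; red points passed the limma test at an adjusted p under 0.05, grey points did not, and black bars are medians of windows of 5 Mb with 8 or more genes. The window from 70 to 75 Mb has a median of −0.88, and the one from 5 to 10 Mb a median of 0.64.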

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

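The settings named below with the dispersion fixed at 1, another dispersion prior, a minimum for the rarer form, limma with no minimum change, summed events, a mean count of 100 or more, the gene lists on the authors' calls under other thresholds, the authors' calls at a mean count of 20 or more and the totals without chromosome 13 were chosen after seeing the data. The count of 0 called events held with mean counts of 10 and 50, no filter, no minimum change, a change of 0.20, limma with the change of 0.10, and adjustment within kinds. It was 3 with limma and no minimum change (2 skipped exons, 1 retained intron) and 2 with a rarer form of 5 or more reads (2 skipped exons). With a prior from rarer forms of 1 or more reads it was 11 (11 skipped exons). With a prior along the total count it was 19 (18 skipped exons, 1 retained intron), and 40 with no minimum change as well (32 skipped exons, 4 retained introns, 3 alternative 5′ sites, 1 alternative 3′ site). With the dispersion fixed at 1 it was 246 (185 skipped exons, 28 mutually exclusive exons, 19 retained introns, 9 alternative 3′ and 5 alternative 5′ sites). By the authors' deposited table it was 294 (224 skipped exons, 28 retained introns, 16 mutually exclusive exons, 15 alternative 3′ and 11 alternative 5′ sites). Leaving out 1 library gave 0 to 5 events, 5 without library 1 of set 1 and 2 without library 3 of set 1 (0 to 3 skipped exons, 0 to 1 mutually exclusive exons, 0 to 1 alternative 5′ sites). The differences between dispersion settings come from how the spread is estimated; the cause of the others was not tested. Of the 50 events named for being called in the authors' deposited table, none passed the quasi-binomial test or limma; with levels from raw counts all 60 named events kept their direction.

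In the authors' deposited table the 294 events became 135 at an adjusted p under 0.01, 145 with a change of 0.20 or more, 515 with no minimum change and 171 with a mean count of 20 or more, as stricter or looser thresholds must. The share of skipped-exon genes higher in set 1, 61.9%, was 58.3% at an adjusted p under 0.01 (adjusted p = 0.312). The share for retained introns, 25.0%, was 50% at an adjusted p under 0.01 (adjusted p = 1.0) and 42.9% with a change of 0.20 or more (adjusted p = 0.988), and 6.25% with a mean count of 20 or more (adjusted p = 0.00259); fewer events enter these tests. The number of gene lists past the threshold, 0, was 1 with the authors' adjusted p under 0.01, 1 with their calls at no minimum change, 1 with their calls at a mean count of 20 or more and 1 with the prior along the total count, each time the cytoskeleton and microtubule list. It was 2 with the dispersion fixed at 1, that list and endocytosis and vesicle traffic. The cause was not tested.

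For junction totals, the 88 genes (49 higher, 39 lower in set 1) were 86 with median-of-ratios scaling, 99 with no filter, 82 with a pseudocount of 0.1, 104 with events summed and 60 with a mean count of 100 or more (23 lower, fewer genes tested). With the genes of chromosome 13 left out before the adjustment of p-values, the lower genes numbered 23. Leaving out 1 library gave 25 to 287 genes, 19 to 122 higher and 6 to 165 lower in set 1. The highest came without library 1 of set 1, in which all 88 genes remained. Of the named genes 15 no longer passed without library 2 of set 1 and 12 without library 2 of set 2. The others were 25 without library 2 and 41 without library 3 of set 1, and 72, 32 and 43 without libraries 1, 2 and 3 of set 2; the cause was not tested. The median of distal chromosome 13, −0.58, stayed between −0.79 and −0.47 with each library left out.

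No paired analysis was possible because the table's columns carry no replicate numbers; a block by position in the lists would rest on an order that no source states, and was not fitted. Like the planned test of edgeR, its alternatives were not run: a DESeq2 test, and TMM factors and DESeq2 size factors on inclusion and skipping columns. The table holds no counts on exon bodies. Of the tested events 69.2% had fewer than 5 reads per library on their rarer form, and 2 of the 12139 others were called with that minimum. Recovery of simulated changes was not measured in those events, so how far scarce reads limit the test stays open.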

Other observations

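The splits of the libraries, the tests on chromosome 13, the choice of the actin list, its camera test and the leave-one-out medians of its uncalled members came after the results were seen.

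The authors' deposited table called 294 events, 171 of them with a mean count of 20 or more. The quasi-binomial test called 0 of the events with that mean count, and 0 with no filter on counts. With the dispersion fixed at 1, so that only binomial sampling noise counted, the real split called 246 events and another of the 10 splits called 267, and the lowest of the others called 70. The split of 267 put library 1 of both sets, the deepest of each, on the same side. Other splits that did so called 191, 250 and 225 events, and those that did not, the real one aside, called 70 to 154. This points to a structure among the libraries, which neither the quasi-binomial test nor the limma test modelled. A test that leaves out variation between libraries can thus call as many events between mixed groups of libraries as between the sets. These numbers bear on the test with the dispersion fixed at 1 alone. How the authors' test treats variation between libraries was not examined, so the source of their calls was not tested. A rarer form below 5 reads was found in 64.6% of the authors' called events, but also in 72.9% of all events, so this share does not decide whether scarce reads matter. For the reported test the real split called 0 events, so all 10 of 10 splits call as many by construction and their number decides nothing; the highest other split called 2.

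For junction totals, 1 of the 10 splits gave 88 or more genes, the real one, and the highest of the others gave 0; the splits are again too few for a share under 0.05. The lower totals on distal chromosome 13 did not rest on the called genes alone, since the other genes of the region had a median log2 ratio of −0.57. Under median-of-ratios scaling the region lay at −0.6 relative to all other genes, a difference that a scale factor hardly moves, so this is no test of scaling. A difference in copy number of the region between the cells of the sets is a candidate explanation. Of the region's uncalled genes, 91.3% lay below 0, and its higher and lower expressed genes had medians of −0.55 and −0.65. Since the region was singled out on these same values, they restate the pattern and do not tell copy number from another cause that acts on the whole region. The 3 libraries of set 1 did not show the shift alike: their medians spanned 0.69, more than the difference of −0.6 between the sets in size. Most of the span comes from library 1, at 0.1 against −0.41 and −0.59, and without that library the region's median log2 ratio was −0.79. With 1 library standing apart, whether a difference in copy number would be shared alike by set 1 stays open. Copy number was not measured here, and an effect of the genotype on the region stays open and untested.

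Of 93 genes of the actin cytoskeleton and its regulator Srf, listed after the first called genes were seen, 59 were measured and 17 called, all 17 higher in set 1, among them Cnn2 at 1.34 ± 0.11 and Srf at 0.73 ± 0.15 (log2 ratio ± SE); the cytoskeleton list fixed beforehand, which shares 12 of the 93, had a median of 0.005 and did not pass camera (adjusted p = 0.527). The 42 members not called had a median log2 ratio of 0.14, at percentile 100 of 10000 random lists of uncalled genes matched on expression, and camera with an estimated correlation gave them p = 0.00672 among uncalled genes. The lowest leave-one-out median of all 59 members was 0.27, against 0.3, but they include the genes behind the choice of the list; for the 42 it ranged from 0.08, without library 1 of set 2, to 0.18. Cells of another type in set 1 remain possible and cannot be told apart, because only 3 of the listed fibroblast and muscle markers were measured, with a median of 0.21 and none called (Sparc at 1.0 ± 0.37, Vim at 0.21 ± 0.14 and Fn1 at −0.27 ± 0.15), while Tnnt2 at 1.66 ± 0.31, Itga7 at 1.22 ± 0.22 and Popdc2 at 3.76 ± 0.31, genes outside that list with known roles in muscle and picked after their values were seen, were called higher. A difference between the sets in this group of genes may be a hypothesis for a further experiment, since the list was chosen on these libraries.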
